A study of Epimedium pseudowushanense with 3 samples.

How the data were processed

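Total RNA from whole seeds of Epimedium pseudowushanense was sequenced as paired-end Illumina libraries, with 1 library at each of 3 developmental stages. RNA was extracted with TRIzol and sequenced on a HiSeq 2500, per the labels' protocols. The stages were seeds whose embryo had started to grow (first stage), seeds whose embryo had passed 0.5 of the seed length (middle stage) and germinating seeds. Each library was assigned to its stage by the developmental stage given in its labels, and each column of the table by its name, which equals the library's title.

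The deposited table gives RPKM values (by its definition, reads per kilobase of transcript and per 1000000 mapped reads), which the authors computed and printed to 2 decimals. It holds 178603 transcripts under identifiers of the form that de novo transcriptome assemblers write, with 178603 distinct components, so each component has 1 transcript. The submitters' processing notes name R 3.1.0. The assembler, the aligner, the counting rule, any use of strand and any filter are not given in the sources used here. No transcript was at 0 in every library (0 transcripts), so the table covers what at least 1 library detected. Transcript lengths, read totals, sequences and gene names were not used here. RPKM divides by each library's total, so a transcript that takes a large share of the reads lowers the values of the others, and short transcripts at low RPKM rest on few reads.

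The depth in reads is therefore unknown, but relative depth could be read from the values. At low levels the RPKM of a transcript falls on steps, the whole multiples of what 1 counted read or read pair is worth. Whether the authors counted reads or pairs, in the values and in the total they divided by, is not given in the sources used here, and relative depth assumes that it was the same for all 3 libraries. The ratio of these steps between libraries was sought over transcripts with values from 0.4 up to 1.2 RPKM in both libraries. Ratios far from 1 were dropped first, so a large gap in depth could not be found. The ratio given is the median of the ratios near their mode. The step was the same in the first and middle libraries (ratio 1.00, from the 1899 near the mode among 11375 low transcripts). It was 1.07 times as large in the germinating library as in the middle one (896 of 6624 low transcripts). Compared with the first library it was also 1.07 times as large (750 of 5726 low transcripts). By this estimate the germinating library had 6.56% fewer mapped reads or pairs than the middle one. On 4 sets of simulated reads with known depth ratios, all near 1, the method erred by at most 0.412%. Larger gaps in depth were not simulated.

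With 1 library per stage there is no replicate error, and no p-value was computed. A transcript counted as higher or lower by a fixed size rule: at least 1 RPKM in the higher library and a difference of at least 1 in log2(RPKM + 1), with a pseudocount of 1. That scale understates the change of low transcripts. The rule was applied to the 3 pairs of stages and to the 2 consecutive steps. Transcripts were also grouped by their mean RPKM over the 3 libraries. The rule was tested on simulated data made from the means of each pair over all 178603 transcripts, with 200 changed transcripts drawn from those with a mean of at least 10 RPKM in the pair, so the recovery holds for that level only. For the first step, 96% of the 100 transcripts changed 3-fold and 100% of the 100 changed 6-fold were called in the right direction. For the last step and for the span from the first to the germinating stage, 97% of the 3-fold and 100% of the 6-fold changes were recovered in each.

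The size of counting error was simulated with 20 draws per pair of libraries in which no transcript changed. The count of values per RPKM interval dropped sharply near 0.3 RPKM in every library. Between intervals of equal width the ratio was 2.89 in the first library, 2.95 in the middle one and 3.36 in the germinating one. A smaller drop lay near 0.15 RPKM: in the first library 6600 values at 0.12 to 0.14 RPKM were followed by 4939 at 0.16 to 0.18 RPKM, a ratio of 1.34, against 2.89 at the larger drop (10041 at 0.26 to 0.28 RPKM and 3472 at 0.30 to 0.32 RPKM). Such steps would arise if a single read were worth up to about 0.15 RPKM and a read pair counted as 2 reads, which the sources used here do not state. Each 0.3 RPKM was taken as 1 counted molecule for every transcript. With 0.15 RPKM, an alternative added after the data were examined, the simulated calls fell from 3990 to 554 at the first step, from 3416 to 446 at the last and from 2693 to 337 over the span. The choice of 0.3 RPKM was made after the data were examined and assigns longer transcripts fewer molecules than they are likely to have. The simulation covers counting error only, without differences between seeds or PCR duplicates.

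The size rule, the alternatives and the rule for naming transcripts were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no minimum and a minimum of 10 RPKM, a size rule of 2 on the log2 scale, and rescaling by median-of-ratios factors, by trimmed means (30% of log ratios and 5% of levels trimmed at each end) or to a sum of 1000000 per library. Leaving out the most abundant transcript was added after the data were examined, with the remaining values rescaled to each library's deposited sum. Rescaling the libraries to equal sums at the geometric mean of the deposited sums was also added then. Sums of 1000000 raise every value and so also lower the effective minimum, whereas equal sums keep the overall level. The naming rule, for a table without gene names, took the 2 transcripts with the greatest increase and the 2 with the greatest decrease from the first to the germinating stage, among those with at least 10 RPKM in the higher library. The 39 gene lists prepared beforehand, which included abscisic acid and gibberellin genes, need gene names and were not analysed here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.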

Results

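Seeds of Epimedium pseudowushanense, a perennial herb of the barberry family, are shed with an underdeveloped embryo and stay dormant until it has grown. The study set out to find genes of abscisic acid and gibberellin metabolism and signalling that act over this period. Abscisic acid is a plant hormone that maintains seed dormancy, and gibberellins are hormones that promote germination. The transcriptome was measured by RNA sequencing of whole seeds at 3 stages: the start of embryo growth, an embryo longer than 0.5 of the seed, and germination. Each stage had 1 library, so every difference below is between single libraries, has no replicate check and carries no p-value. Transcripts are identified by assembly number, without gene names or genome positions, and individual hormone genes were not analysed here.

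The middle stage had the most transcripts with a value above 0 and the germinating stage the fewest. Of 178603 transcripts, 134657 (75.4%) were above 0 RPKM when the embryo started to grow, 148343 (83.1%) at the middle stage and 87582 (49.0%) in germinating seeds. The order changed with the level. At 10 RPKM or more there were 6393 transcripts at the first stage, 7599 at the middle stage and 7726 at germination, and at 100 RPKM or more there were 654, 796 and 930. By the steps of low values, compared only for ratios near 1, the mapped depth of the germinating library was 6.56% below that of the middle library. The first and middle libraries did not differ by this measure.

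**Figure D1:**
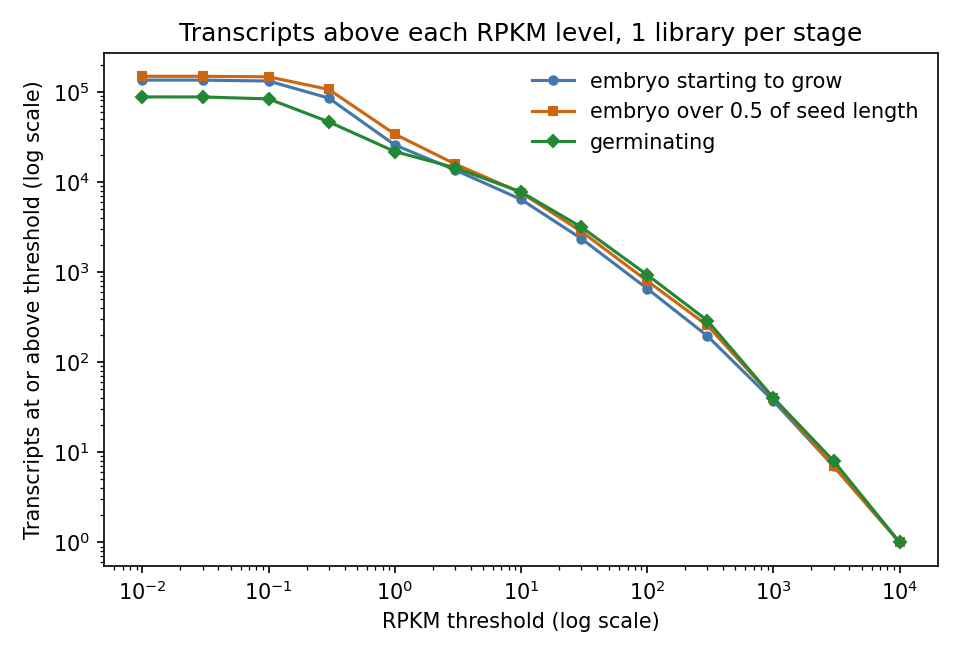
Number of transcripts (y axis, log scale) at or above each RPKM threshold (x axis, log scale) in the single library of each stage. The germinating library lies lowest at low thresholds, with 21705 transcripts at 1 RPKM or more against 33885 at the middle stage, and highest at 100 RPKM or more, with 930 against 796.

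Detection overlapped in part between the stages. All 3 libraries shared 61674 transcripts (34.5%), and 45223 (25.3%) were above 0 at the first and middle stages but listed at 0 in germinating seeds. The middle library alone held 28686 transcripts, the first library alone 17112 and the germinating library alone 2500. Transcripts restricted to 1 stage were mostly weak. Among those of the middle library alone, 88.2% stayed under 1 RPKM and 12 reached 10 RPKM. Among those of the first and the germinating library alone, 8 and 6 reached 10 RPKM.

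The same transcript was the most abundant at every stage. It had 57185 RPKM at the start of embryo growth, 40042 at the middle stage and 34698 at germination, or 10.6%, 6.39% and 5.64% of the summed RPKM of each library. The 100 most abundant transcripts of each library made up 31.8% of the summed RPKM at the first stage, 25.6% at the middle stage and 26.0% at germination.

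The first comparison asked what changed while the embryo grew past 0.5 of the seed length. More transcripts were higher than lower at the middle stage. Of 39729 transcripts with at least 1 RPKM in either library, 10860 were higher and 2915 lower, so that 78.8% of the changed transcripts were higher. In each class of mean RPKM, higher transcripts outnumbered lower ones as deposited and under median-of-ratios, trimmed-mean and equal-sums rescaling. Among transcripts with a mean of 1 to 10 RPKM, 3164 were higher and 874 lower, with a median log2 difference of 0.19. Between 10 and 100 RPKM, 1145 were higher and 308 lower (median 0.27), and at 100 RPKM or more the numbers were 199 and 47 of 787 transcripts, with a median log2 difference of 0.51 (interquartile range 0.06 to 1.03). Of the higher transcripts, 4330 were listed at 0 at the first stage. Libraries simulated with counting error alone, at 0.3 RPKM per counted molecule, gave 3990 calls on average (554 at 0.15 RPKM per molecule), against 13775 observed, and 9.45 against 1699 among transcripts of 10 RPKM or more. The share higher depended on scaling. It was 73.8% after median-of-ratios rescaling, which moved the median log2 difference of the transcripts with at least 1 RPKM in either library from 0.40 to 0.24, 64.8% after trimmed-mean rescaling, which moved it to 0.04, and 68.0% after rescaling to equal sums. Over all 178603 transcripts the median as deposited was 0.11.

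The last step compared germinating seeds with the middle stage, and its direction differed with transcript level. Over all 36306 transcripts with at least 1 RPKM, 1906 were higher and 11239 lower in germinating seeds (85.5% of changed transcripts lower), and 6976 of the lower ones were listed at 0 there. Of the 16889 transcripts with a mean of 1 to 10 RPKM, 894 were higher and 2539 lower. Of the 7385 transcripts with a mean of 10 RPKM or more, 542 were higher and 333 lower. At 100 RPKM or more the numbers were 66 and 74. This balance turned to 119 and 56 after median-of-ratios rescaling and to 116 and 57 with trimmed means. Equal sums left it nearly even, at 68 and 73. Counting error alone, at 0.3 RPKM per counted molecule, gave 3416 calls on average (446 at 0.15 RPKM per molecule), against 13145 observed. At 10 RPKM or more it gave 5.75 at the 0.3 RPKM setting, against 875 observed. By direction that setting gave 1695 higher and 1721 lower calls, against 1906 and 11239 observed. The observed higher calls over all levels were thus little more than counting error alone gave at 0.3 RPKM. With 0.15 RPKM per molecule the simulated calls were 194.5 higher and 251.8 lower. Rescaling moved the split over all transcripts with at least 1 RPKM to 73.8% lower with median-of-ratios factors and 73.6% with trimmed means, and the median log2 difference of this set from -0.30 to 0.06 in both. As deposited and under median-of-ratios, trimmed-mean and equal-sums rescaling, the share lower among changed transcripts of 1 to 10 RPKM lay between 61.5% and 74.0%. At 10 RPKM or more the share higher lay between 61.9% and 78.8%.

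From the start of embryo growth to germination, abundant transcripts were more often higher than lower. Of the 7385 transcripts with a mean of 10 RPKM or more, 2109 were higher and 726 lower, which made 74.4% of the changed ones higher. Under median-of-ratios, trimmed-mean and equal-sums rescaling this share lay between 65.9% and 81.3%. At 100 RPKM or more, 277 of 787 transcripts were higher and 98 lower, with a median log2 difference of 0.60 (interquartile range -0.13 to 1.40). Counting error alone, at 0.3 RPKM per counted molecule, gave 7.25 calls on average at 10 RPKM or more, against 2835 observed. Over all 29648 transcripts with at least 1 RPKM the numbers were nearly even, with 5681 higher and 5509 lower. The balance of that wider set had no fixed direction, since 59.5% were higher after median-of-ratios rescaling, 40.0% after rescaling to equal sums and 23.6% after rescaling to sums of 1000000, which also lowers the effective minimum.

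**Figure D2:**
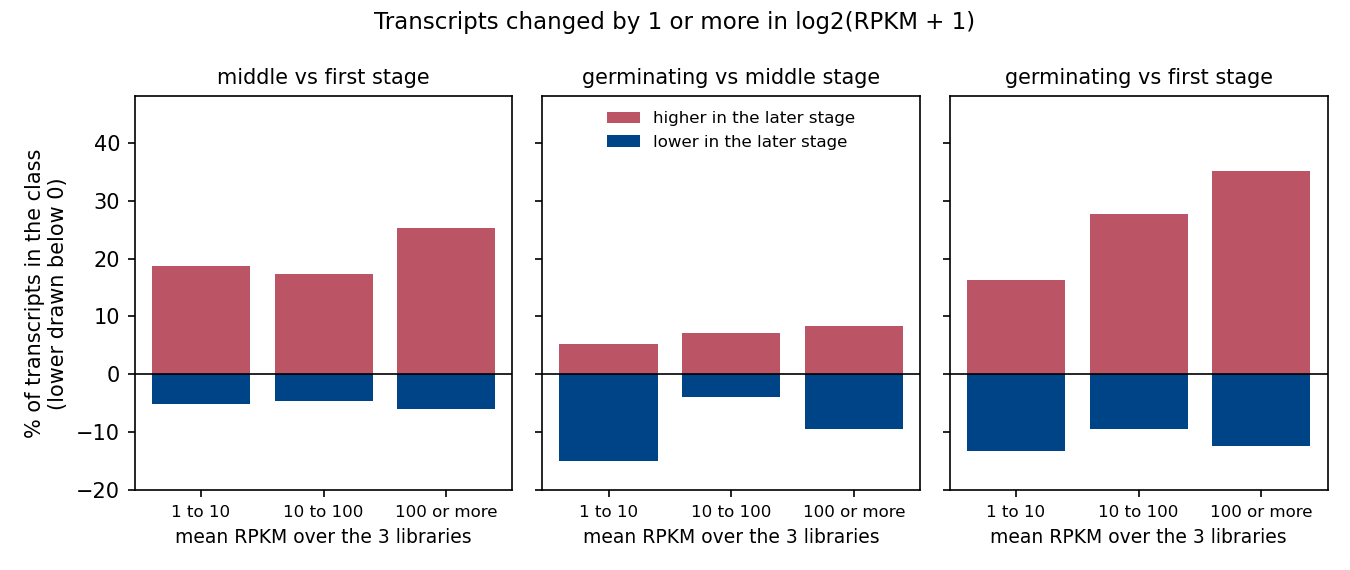
Percent of transcripts (y axis) that were higher (drawn above 0) or lower (drawn below 0) in the later stage of each pair by at least 1 in log2(RPKM + 1), in classes of mean RPKM over the 3 libraries (x axis). Higher transcripts outnumber lower ones in all 3 classes of the first step and of the whole span (in the class of 1 to 10 RPKM of the span this turned to 2378 higher and 2720 lower after rescaling to equal sums), whereas at the last step the class of 1 to 10 RPKM holds 2539 lower and 894 higher transcripts.

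The greatest increases ran through both steps. The transcript comp43661_c0_seq1 had 0.69 RPKM at the start of embryo growth, 66.5 RPKM at the middle stage and 1285 RPKM in germinating seeds, where it ranked 25. Its log2(RPKM + 1) was higher by 5.32 at the first step and by 4.25 at the last, in all by 9.57. The transcript comp51489_c0_seq1 had 1.49, 140 and 999 RPKM, with log2 differences of 5.82 and 2.83 for the steps and 8.65 in all.

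The greatest decreases also ran through both steps. The transcript comp30033_c0_seq1 had 455 RPKM at the first stage, where it ranked 118, then 120 RPKM and 0.69 RPKM. Most of its log2 difference of -8.08 lay in the last step (-6.16, against -1.92 in the first). The transcript comp12098_c0_seq1 had 218, 16.3 and 0.53 RPKM, with differences of -3.66 and -3.50 for the steps and -7.16 in all. The lowest values of all 4 transcripts may rest on few reads, which cannot be told without transcript lengths, so linear ratios are not given. Of 8815 transcripts with at least 10 RPKM in the higher library, 215 were higher and 55 lower by 4 or more on this log2 scale.

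**Figure D3:**
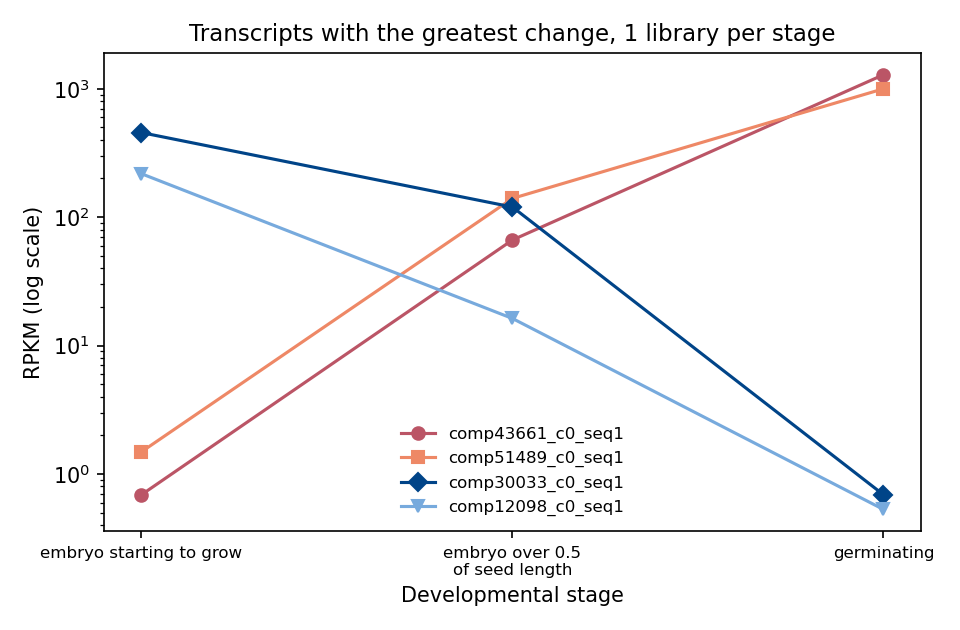
RPKM (y axis, log scale) of the 2 transcripts with the greatest increase and the 2 with the greatest decrease from the first to the germinating stage, at the 3 stages (x axis), with 1 library per point. In all 4 transcripts the middle stage lies between the others, as with 66.5 RPKM between 0.69 and 1285 RPKM in comp43661_c0_seq1.

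The middle stage was in most cases intermediate for abundant transcripts that differed between the ends of the series. Of the 2835 such transcripts with a mean of 10 RPKM or more, 2566 (90.5%) had a middle value between the other two. When the 3 values of each transcript were put in random order, the mean share was 55.4% and the highest of 100 draws 57.8%. Each transcript was reordered separately, so this range leaves out shifts of a whole library and does not measure the spread between libraries. Under median-of-ratios, trimmed-mean and equal-sums rescaling the share lay between 89.4% and 91.8%. Of the 7815 such transcripts with a mean of 1 RPKM or more, the share was 83.4%.

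By trajectory over the 2 steps, 550 transcripts were higher at both steps and 174 lower at both. A further 7588 were higher at the middle stage and then lower again, and 46 were lower and then higher. In the same order, median-of-ratios rescaling gave 784, 130, 6017 and 74. Other scalings were not applied to the trajectories. Trimmed means left 7353 transcripts higher at the first step, so the group higher then lower would be smaller than 7588 there. The steps share the middle library, so an error in it shifts them in opposite directions. Simulated libraries with counting error alone, at 0.3 RPKM per counted molecule, gave on average 0.1 transcripts higher at both steps and 0.2 lower at both. They gave 428 higher then lower and 201 lower then higher. The trajectories were not simulated at 0.15 RPKM per molecule, a setting that gave fewer calls at each step. Random order of the 3 values gave on average 169 higher at both, 169 lower at both, 3934 higher then lower and 1202 lower then higher. Independent lists of the same sizes would share 496, 784, 2922 and 133 transcripts. The simulation and the random order use the same middle value in both steps, and the independent lists do not. None of them models a shift of the whole middle library, so part of the excess higher then lower may come from it. The 46 transcripts lower then higher were fewer than all of these numbers for that trajectory. The transient group consisted mainly of weak transcripts, with 125 of the 7588 at a mean of 10 RPKM or more. In that class of abundance, 329 transcripts were higher at both steps and 116 lower at both, and 890 were higher at the first step only.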

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

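Counts are given as higher, then lower. With a pseudocount of 0.1, 5562 transcripts were lower at the first step, 3013 higher at the last step and 8892 lower over the whole span, and the trajectory counts were 363 lower at both steps, 11535 higher then lower and 149 lower then higher. The 4 named transcripts kept their direction, with log2 differences of 10.67, 9.30, -9.17 and -8.43. With a pseudocount of 5 the counts were 1597 and 396 for the first step, 692 and 967 for the last, and 2598 and 897 for the span. With a minimum of 10 RPKM they were 1660 and 518, 819 and 652, and 2786 and 965, so the last step turned from mostly lower to mostly higher, and the trajectories held 244 higher at both, 95 lower at both, 424 higher then lower and 17 lower then higher. With a size rule of 2 the counts were 1349 and 245, 385 and 1369, and 1615 and 648, with trajectories of 59, 23, 726 and 0. The pseudocounts and the minimum remove or add weak transcripts by construction. The size rule of 2 instead removes differences from 1 up to 2 on the log2 scale at every level. Median-of-ratios rescaling gave 3178 higher at the last step and 74 lower then higher, and trimmed means gave 2867 higher at the last step. Sums of 1000000, which raise all values and so let weaker transcripts pass the minimum, gave 23440 and 14717 for the first step, 3334 and 28209 for the last, and 6826 and 22103 over the span, which turned to mostly lower. Leaving out the most abundant transcript included rescaling the others to each library's deposited sum. With this setting and with equal sums, both chosen after seeing the data, the 6 counts stayed within 1.5 times. The span again turned to mostly lower in both (5513 and 7034, and 4843 and 7267), as it did with a pseudocount of 0.1 (7309 and 8892). At 1 RPKM or more, 25690, 33885 and 21705 transcripts were detected at the first, middle and germinating stages. Having no minimum changed nothing, since the size rule already requires 1 RPKM. Of 82 recomputed counts, 39 stayed within 1.5 times of those reported and 43 moved by more. The alternative of 1 transcript per gene had nothing to merge, the gene lists were not run for lack of names, and leaving out a replicate was not possible with 1 library per stage. Depth limits values under 1 RPKM, where short transcripts rest on few reads.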

Other observations

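The tests of depth, of a few dominant transcripts, of another source of reads and of transcripts near the floor were chosen after the result had been seen, as were the rescaling to equal sums, the shuffles inside blocks of rows and the simulation with 0.15 RPKM per molecule. The tests of counting error, the other scalings and the shuffles within levels were chosen before. Each stage had 1 library, so a difference between seed lots or library preparations cannot be separated from the stage in any pattern.

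Germinating seeds had 41.0% fewer transcripts above 0 RPKM than the middle stage. The estimated gap in depth would allow a loss of at most 6.56% of the transcripts. That estimate considered only ratios near 1 and could not have shown a gap large enough for this loss. It therefore does not decide whether lower depth accounts for it. The most common value above 0, sought without that limit, was 0.25 RPKM in the middle library and 0.27 RPKM in the germinating one, which gives no sign of a large gap. The summed RPKM outside the 100 most abundant transcripts was 0.978 times that of the middle library. The 1000 most abundant made up 57.6% of the summed RPKM, against 53.6% at the middle stage. RPKM is divided by transcript length, and lengths were not used here. Whether a few transcripts took most of the counted reads therefore cannot be told from these sums. Reads from another source in the earlier libraries, such as genomic DNA or other organisms, may account for the loss and stay open, as does a narrower set of transcribed genes at germination. Of the 45223 transcripts above 0 in both earlier libraries and listed at 0 in germinating seeds, 89.9% were under 1 RPKM, and without names or sequences their origin cannot be told apart.

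At the first step 78.8% of the changed transcripts were higher at the middle stage. Transcripts near the floor are not the whole reason, since 76.2% were still higher with a minimum of 10 RPKM. Scaling between the libraries is a candidate explanation for part of the excess: trimmed means gave the lowest share of 3 scalings that keep the overall level, 64.8%, just under the 65% set in advance, and higher transcripts remained the majority. Simulated unchanged libraries gave 29.0% as many calls as observed, between the bounds of 10% and 50% set in advance, but a number of calls does not bear on direction, and the simulated calls were balanced (1991 higher and 1999 lower on average). With 0.15 instead of 0.3 RPKM per molecule the simulated calls were 4.02% of the observed. The stage itself is untested for lack of replicates.

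At the last step 74.0% of the changed transcripts with a mean of 1 to 10 RPKM were lower in germinating seeds, against 38.1% of those with a mean of 10 RPKM or more. Scaling does not close this gap of 35.9 percentage points, which was at least 37.0 points under 3 other scalings. Simulated unchanged libraries gave 25.4% as many calls at 1 to 10 RPKM as observed, again between 10% and 50%, which does not bear on direction either, and the simulated calls at all levels were balanced (1695 higher and 1721 lower on average). With 0.15 RPKM per molecule the calls at 1 to 10 RPKM were 114 on average, against 3433 observed, and those at all levels were less even (194.5 higher and 251.8 lower). At that level 2539 transcripts were lower and 603 were listed at 0 in germinating seeds, so most of the lower ones were still detected there. The stage itself is untested.

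Neighbouring assembly numbers were examined for a hidden grouping of transcripts. One hypothesis was that neighbouring numbers are pieces of the same or related transcripts and so change alike. It found no support: over 2293 neighbouring pairs with a mean of 10 RPKM or more, the Spearman correlation across transcripts of the change from the first to the germinating stage was 0.0064, within the range of 100 shuffles (-0.05 to 0.05). A second hypothesis was that transcripts above 0 in the middle library alone come from a separate source assembled together. They formed 6294 adjacent pairs, above the highest of 100 shuffles within levels (6062), as that hypothesis predicted. They were within the range of 100 shuffles inside blocks of 1000 rows, both without levels held (6028 to 6383) and within levels (6064 to 6336). Shuffles that keep each block's share thus gave as many pairs. The share was 6.70% in the first of 10 equal parts, 2.09% in the second and 27.6% in the last, and the source stays open.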
